A study of Mus musculus with 6 samples.

How the data were processed

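Gene expression was measured by sequencing of messenger RNA in mouse group 2 innate lymphoid cells (ILC2), sorted as lineage-negative cells carrying Thy1 and ST2, from homozygous Id1 transgenic mice. The labels name 3 groups of 2 libraries each: cells taken directly from the thymus, cells taken directly from mesenteric lymph nodes (MLN), and MLN cells cultured for 1 week in IL-7, IL-25 and IL-33 at 10 ng/ml each. Per the labels, about 300000 cells went into each sample and a stranded mRNA kit was used. The deposited files give, per library, a raw count of reads for each Ensembl gene, with no normalization applied. The submitters' processing notes name HTSeq 0.5.3p9 and the mouse builds mm9 and NCBIM37; the aligner, the annotation release and the strand setting are not given in the sources used here. The unit was checked on the values, which were whole numbers, and 0 of the 37991 entries named anything other than a gene. Symbols and biotypes were matched by Ensembl identifier to a later annotation (GENCODE M21), which gave 32919 identifiers a symbol and left 5072 without. No coordinates were taken from it, since the counts were made on an older build. Because the strand setting is unknown, counts of genes that overlap on opposite strands are uncertain, as are those of near-identical copies such as Gapdh and ribosomal protein genes with pseudogenes, Hspa1a and Hspa1b, Ifit3 and Ifit3b, and the T cell receptor constant genes.

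Library totals ran from 35280692 to 40578264 counts. Genes with too few counts were removed with the default rule of filterByExpr in edgeR, which left 16231 of the 23871 genes with a count in any library. Libraries were scaled with TMM factors, and CPM values are normalised read counts on these TMM-scaled library totals. All 6 libraries were fitted together with 1 mean per group and no block, in R 4.3.3 with edgeR 4.0.16, with the quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjustment over all genes tested within each comparison. A gene is called when its adjusted p is under 0.05, and words such as rose, fell, higher and lower are used of called genes. The fit had 3 residual degrees of freedom, a prior of 9.54 degrees of freedom and a common biological coefficient of variation of 0.066. Adjusted p values of single genes come from this edgeR test throughout. The error (SE) of a log2 fold change is the absolute log2 fold change divided by the square root of the F statistic of its test. It can be too small where the change is large and the lower group has few counts. Csn2, a casein gene with 9 counts over fresh MLN, had an error of 0.51 against thymus and 0.14 against cultured cells. Errors of CPM values are standard deviations of the 2 libraries of a group. The labels do not say whether the 2 libraries of a group come from separate animals or separate cultures, so p values measure only the spread between these libraries. With 2 libraries against 2, a permutation of a single value cannot reach p = 0.05, so no such test was run.

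The gene lists, 35 in number, were written from textbook knowledge before the data were examined, as were the comparisons, the tests, the alternative settings and the rule for naming genes. They fall into 3 kinds and cover programs the organ or the cytokines can bear on, markers of other cell types, and technical groups of genes. Each list was tested with camera in limma 3.58.1 on voom values, with the preset correlation of 0.01 between genes and adjustment over the lists within a comparison. Beside the number of members called over all genes stands the number called when p values were adjusted over the list alone. Camera with a correlation estimated per list and fry were run as alternatives; fry asks whether the genes of a list move one way on balance, without comparing them with other genes.

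The rule for named genes took the 6 highest and 6 lowest log2 fold changes among called genes with a symbol, at least 10 CPM in the higher group and no overlap between the groups. It then took up to 3 called members of each list with the largest change and at least 5 CPM in the higher group, or the most abundant member where none passed, with the 2 most abundant members of lists for other cell types. It always included Id1, Gata3, Il1rl1, Thy1, Il7r, Rora, Il5 and Il13. Genes outside this rule are named as chosen after their values were seen. A fold against a group without counts is a lower bound computed with 3 counts over that group and is written as "at least". Against 1 to 3 counts the ratio of counts is given with an exact 95% counting interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. In a single library 3 counts equal between 0.0739 and 0.0905 CPM.

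The alternatives were RLE factors, upper-quartile factors, library totals alone, no filter, a filter of at least 5 CPM in 2 libraries, protein-coding genes only, a test against a 2-fold change, a replicate block, a fit to the 4 libraries compared, DESeq2 1.42.0, and leaving out each library in turn. Library totals alone moved the median log2 difference of all genes by -0.218 between cultured and fresh MLN cells and by -0.251 between cultured MLN and thymus cells. Changes after culture are therefore stated relative to the TMM scale. The pipeline was tested on simulated data in which 200 of 16231 genes were changed, 50 at each of 4 sizes. In the comparison of thymus with MLN it called 74% of the genes changed 1.5-fold, 98% of those changed 2-fold, and 100% of those changed 4-fold or 8-fold, with 13 of 16031 unchanged genes called. In the comparison of cultured with fresh MLN these shares were 74%, 90% and 100%, with 16 unchanged genes called. In the comparison of cultured MLN with thymus they were 86%, 90% and 100%, with 15 unchanged genes called. In the data the edgeR test called 47.3%, 77.6% and 72.7% of genes in these comparisons, in the same order. Scaling and the estimate of the spread were thus tested only where most genes were unchanged. These shares and numbers of wrong calls may not hold for the data. In each comparison 5 of 5 simulated lists of 20 genes raised 2-fold were called, and 0 of 20 unchanged lists. Members of these lists varied independently. In the data the estimated correlation was as high as 0.545, for interferon-stimulated genes in thymus against MLN. The simulations therefore do not show how often correlated lists are called wrongly.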

Results

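The data are counts of messenger RNA reads per gene from 6 libraries of ILC2, the innate lymphoid cells that make type 2 cytokines. All cells came from mice homozygous for a transgene that expresses Id1, an inhibitor of E protein transcription factors, from the proximal promoter of lck. There were 2 libraries from thymus, 2 from fresh MLN and 2 from MLN cells cultured for 1 week with IL-7, IL-25 and IL-33. Library totals were 37799166 and 35280692 counts in thymus, 37223939 and 36103469 in fresh MLN, and 37035291 and 40578264 in cultured cells. Across genes, log2 CPM values of the 2 libraries of a group correlated with a Pearson r of 0.9938 in thymus, 0.9935 in fresh MLN and 0.9942 in cultured cells. Between thymus and fresh MLN libraries r lay between 0.9554 and 0.9585, and between cultured and fresh MLN libraries between 0.7985 and 0.8044. Genes are not independent replicates, so these r values describe the libraries only.

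**Figure D1:**
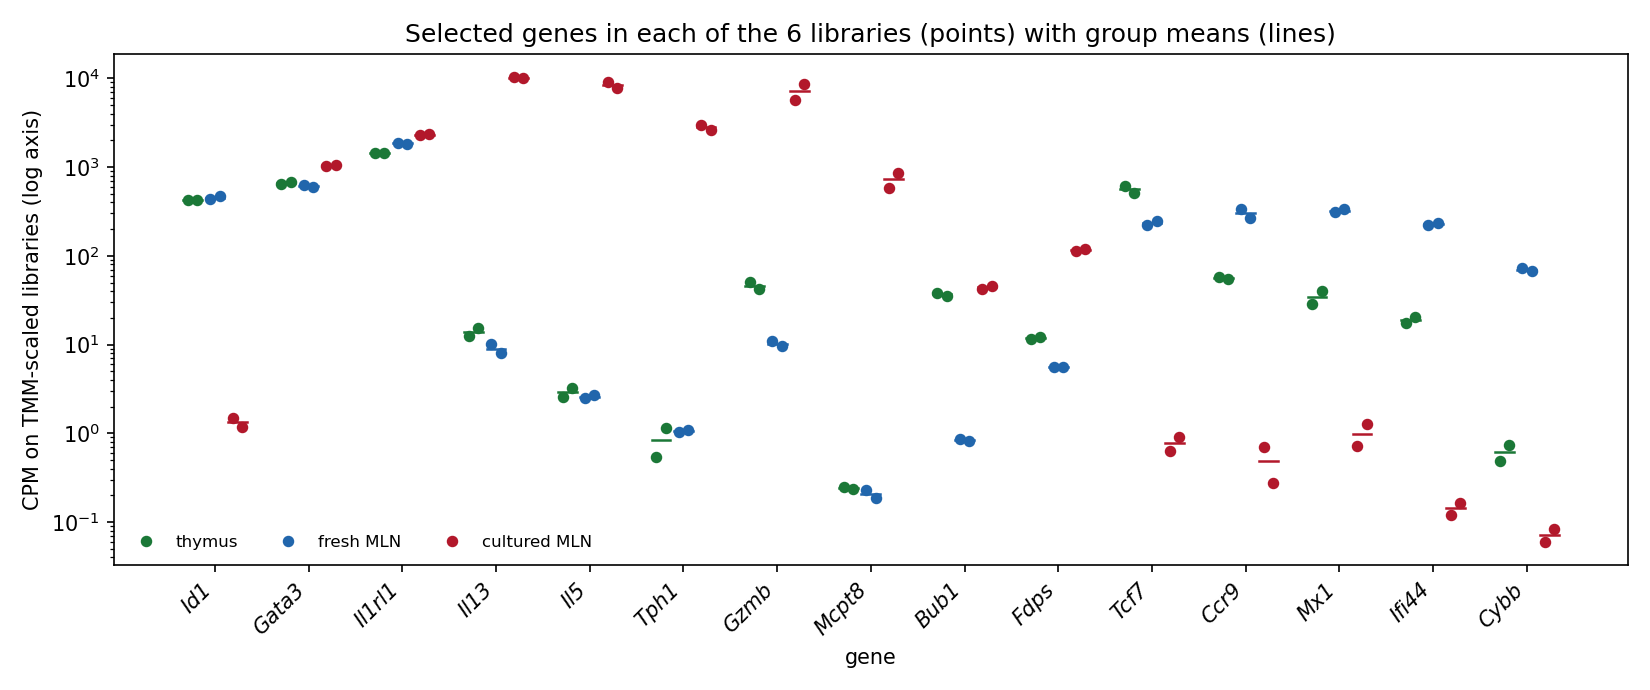
Normalised read counts (CPM, log axis) of 15 genes in each of the 6 libraries, with points for libraries and lines for the mean of each group of 2. Id1 was near 451 CPM in fresh MLN, 424 in thymus and 1.33 in cultured cells.

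The comparison of thymus with fresh MLN asks how ILC2 taken from the organ in which T cells develop differ from those of a peripheral lymphoid organ. Thymus cells had higher levels of all 38 cell cycle genes measured and of 16 of 21 genes that mark early thymocytes, and fresh MLN cells had higher levels of interferon-stimulated genes. Bub1, a kinase of the spindle checkpoint, was 36.9 CPM ± 2.03 in thymus and 0.848 ± 0.0357 in MLN (SD, n = 2 per group), a 43.3-fold difference. Myb, a transcription factor of blood progenitors, was 76.8 CPM ± 10.9 in thymus and 0.731 ± 0.0569 in MLN (SD, n = 2 per group), a 105-fold difference. Mx1, an antiviral GTPase induced by interferon, was 34.2 CPM ± 7.90 in thymus and 323 ± 17.3 in MLN (SD, n = 2 per group). The edgeR test called 7677 of 16231 genes, 47.3% of those tested, of which 4105 were higher and 3572 lower in thymus. The share of called genes that were higher was 53.5%, and 49.7% to 58.4% with the other scalings, so the scaling decides which direction has more calls. A test against a 2-fold change called 897 higher and 401 lower. The 2 groups did not overlap for 72.8% of the genes tested, where chance gives 33.3%.

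Genes that mark ILC2 and the sort were measured at high levels in both organs. Id1 (ENSMUSG00000042745) was 424 CPM ± 3.36 in thymus and 451 ± 24.4 in MLN (SD, n = 2 per group), a log2 fold change of -0.09 ± 0.07 that was not called (adjusted p = 0.32). Gata3 (ENSMUSG00000015619), the transcription factor that ILC2 depend on, was not called either, at 660 CPM in thymus and 611 in MLN (adjusted p = 0.2). Rora (ENSMUSG00000032238), another factor required for ILC2, had a log2 fold change of 0.23 ± 0.12 (adjusted p = 0.13). Il1rl1 (ENSMUSG00000026069), which encodes the ST2 chain of the IL-33 receptor, was lower in thymus by a log2 fold change of -0.35 ± 0.07. Il7r (ENSMUSG00000003882), the IL-7 receptor chain, was also lower, at -0.67 ± 0.08, while Thy1 (ENSMUSG00000032011), the other sort marker, was higher at 1.12 ± 0.10. Of 25 measured genes of ILC2 identity, 8 rose, 11 fell and 6 did not pass, and 19 passed when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.48). Il18r1, a chain of the IL-18 receptor, was 262 CPM ± 4.63 in thymus against 42.9 ± 4.89 in MLN (SD, n = 2 per group). Klrg1, an inhibitory receptor of mature ILC2, had a log2 fold change of -1.33 ± 0.09 and Icosl, the ligand of ICOS, one of -1.57 ± 0.07. Of 6 genes of E proteins and Id proteins 3 rose and 1 fell, with 4 passing when adjusted over the list alone (camera adjusted p = 0.648). Id2 was lower in thymus at -0.88 ± 0.07, and the E protein gene Tcf3 was higher at 0.52 ± 0.06. Id3, chosen after its values were seen, was higher by a counting ratio of 13.1 (95% interval 4.16 to 66), against 3 counts over MLN.

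Genes for secreted products of type 2 responses moved in both directions, with 5 of 21 higher and 7 lower in thymus and 12 passing when adjusted over the list alone (camera adjusted p = 0.426). Il13 (ENSMUSG00000020383), which drives mucus and goblet cell responses, was 14.0 CPM ± 2.27 in thymus and 9.03 ± 1.51 in MLN (SD, n = 2 per group, adjusted p = 0.0017). Il5 (ENSMUSG00000036117), the eosinophil growth factor, was 2.90 CPM in thymus and 2.60 in MLN and was not called (adjusted p = 0.48). Calca, which encodes the neuropeptide CGRP, had a log2 fold change of 2.86 ± 0.17. The cytokine Il6 and the chemokine Ccl5 were lower in thymus, with log2 fold changes of -1.80 ± 0.13 and -2.16 ± 0.12.

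All 38 measured cell cycle genes were higher in thymus, and 38 passed when adjusted over the list alone. Their median log2 fold change was 3.66 (camera adjusted p = 1.92e-31, and adjusted p = 0.329 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, had a log2 fold change of 5.68 ± 0.16. Cenpf, a centromere protein, had one of 5.07 ± 0.10. Pbk, E2f8 and Mxd3, which act in proliferating cells, were among the 6 genes with the highest log2 fold changes of those at 10 CPM or more in thymus and without overlap between the groups, at 5.95, 5.91 and 5.70. Of 18 glycolysis genes 12 rose and 2 fell, with 14 passing when adjusted over the list alone, among them Ldha, lactate dehydrogenase, at a log2 fold change of 1.22 ± 0.08 and Hk2, hexokinase, at 1.30 ± 0.13. The median of this list was 0.48 (camera adjusted p = 0.00195, and adjusted p = 0.329 with an estimated correlation). Of 21 nuclear genes of oxidative phosphorylation 18 rose, with 18 passing when adjusted over the list alone and a median of 0.34 (camera adjusted p = 9.54e-05, and adjusted p = 0.62 with an estimated correlation). Mitochondrial genome transcripts, heat shock genes and cytosolic ribosomal protein genes were listed as technical groups in all comparisons. Whether cell handling or library quality moved them was not tested. All 7 measured transcripts of the mitochondrial genome rose, with 7 passing when adjusted over the list alone and a median of 0.91 (camera adjusted p = 1.25e-05, and adjusted p = 0.329 with an estimated correlation). Of 11 heat shock genes 6 rose, with 6 passing when adjusted over the list alone, among them Hsp90aa1, a cytosolic chaperone, at a log2 fold change of 1.10 ± 0.13 (camera adjusted p = 0.0271, and adjusted p = 0.329 with an estimated correlation). Of 60 genes for cytosolic ribosomal proteins 29 fell and 2 rose, with 31 passing when adjusted over the list alone and a median of -0.22 (camera adjusted p = 0.000201, and adjusted p = 0.699 with an estimated correlation).

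Of 21 early thymocyte genes, 16 were higher in thymus and none was lower, with 16 passing when adjusted over the list alone. The median log2 fold change was 1.43 (camera adjusted p = 5.18e-06, and adjusted p = 0.329 with an estimated correlation). Beside Myb, the list held Bcl11a and Hhex, transcription factors of lymphoid progenitors, at log2 fold changes of 4.82 ± 0.38 and 3.95 ± 0.27. Tcf7, which encodes TCF-1, a factor of both T cell and ILC development, was 564 CPM ± 69.3 in thymus and 234 ± 19.2 in MLN (SD, n = 2 per group). Other thymocyte genes were chosen after their values were seen. Rag1 and Rag2, which rearrange antigen receptor genes, stood at 0.528 CPM ± 0.333 and 0.600 ± 0.0582 in thymus (SD, n = 2) and had 1 count each over the MLN libraries. They were higher in thymus by counting ratios of 41.1 (95% interval 6.99 to 1660) and 46.0 (7.87 to 1860), with adjusted p of 0.0014 and 0.00031. With either thymus library left out the ratio of Rag1 was 22.4 or 58.5, so it was large with each library alone. The sizes of both ratios rest on the 1 count over the MLN libraries. Dntt, the terminal transferase, was higher at 0.849 CPM in thymus and 0.0788 in MLN, a log2 fold change of 3.39 ± 0.63 (adjusted p = 0.00069). Cd8a, at 0.585 CPM in thymus and 0.404 in MLN, was not called (adjusted p = 0.37), and Ptcra, the pre-T cell receptor chain, had 0 counts in thymus. Of 10 Notch target genes 5 rose, with 5 passing when adjusted over the list alone, among them Hey1, a transcriptional repressor, at a log2 fold change of 4.25 ± 0.22 and Nrarp, a feedback inhibitor of Notch, at 0.79 ± 0.13. Tcf7 and Dtx1 belong to this list and to the early thymocyte list, and both were higher in thymus, so the 2 lists are not independent. The list of Notch targets was called with camera adjusted p = 0.0463, and adjusted p = 0.329 with an estimated correlation. The call was lost with RLE factors (adjusted p = 0.0542), without cultured MLN replicate 1 (0.0588) and without cultured MLN replicate 2 (0.0586). Of 25 genes of the T cell receptor complex and its signalling, 13 rose and 5 fell, with 18 passing when adjusted over the list alone and no call for the list (camera adjusted p = 0.123). Cd28, the costimulatory receptor of T cells, was 26.1 CPM ± 5.15 in thymus against 2.71 ± 0.192 in MLN (SD, n = 2 per group).

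All 26 measured interferon-stimulated genes were lower in thymus than in fresh MLN, and 26 passed when adjusted over the list alone. Their median log2 fold change was -1.60 (camera adjusted p = 5.11e-22, and adjusted p = 0.329 with an estimated correlation). Ifit3, an antiviral effector, had a log2 fold change of -4.43 ± 0.21 and Ifi44 one of -3.59 ± 0.08. Markers of myeloid cells moved with them. Of 15 macrophage and monocyte genes 9 fell, with 12 passing when adjusted over the list alone and a median of -1.24 (camera adjusted p = 0.00195, and adjusted p = 0.62 with an estimated correlation). Cybb, the phagocyte oxidase subunit, was 0.619 CPM ± 0.178 in thymus and 69.5 ± 3.85 in MLN, and Lyz2, lysozyme, was 1.80 ± 1.33 in thymus and 10.8 ± 4.07 in MLN (SD, n = 2 per group). Cst3, cystatin C, which macrophages express strongly, was not called, at 71.6 CPM in thymus and 62.8 in MLN (adjusted p = 0.075). Of 10 dendritic cell genes 6 fell and 2 rose, with 8 passing when adjusted over the list alone, among them Fscn1, an actin-bundling protein, at a log2 fold change of -4.57 ± 0.22 (camera adjusted p = 0.0463, and adjusted p = 0.329 with an estimated correlation). That call was lost with RLE factors (adjusted p = 0.0598), with a replicate block (0.0585), without cultured MLN replicate 1 (0.0601) or 2 (0.0594), and without thymus replicate 1 (0.0752).

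Of 12 genes of MHC class II presentation 9 fell and 2 rose, with 11 passing when adjusted over the list alone and a median of -0.85 (camera adjusted p = 0.0145, and adjusted p = 0.329 with an estimated correlation). Cd74, the invariant chain, was 8.06 CPM ± 2.33 in thymus and 43.5 ± 0.0700 in MLN (SD, n = 2 per group). Of 10 B cell genes 5 fell and 3 rose, with 8 passing when adjusted over the list alone. That list was not called (camera adjusted p = 0.513), and its median of -0.66 and mean of 0.51 differed in sign. Ighm, the heavy chain of IgM, was 57.1 CPM ± 1.91 in thymus and 161 ± 27.7 in MLN (SD, n = 2 per group). Cd79b, a chain of the B cell receptor, was higher in thymus at 0.52 ± 0.16. Of 20 NF-kB target genes 14 fell and 2 rose, with 16 passing when adjusted over the list alone and a median of -0.52 (camera adjusted p = 1.39e-05, and adjusted p = 0.473 with an estimated correlation). Icam1, an adhesion molecule, had a log2 fold change of -1.70 ± 0.13, while Tnf, the inflammatory cytokine, was higher in thymus at 1.79 ± 0.19. Of 17 genes of NK cells and ILC1, 11 fell and 3 rose, with 15 passing when adjusted over the list alone and a median of -1.71 (camera adjusted p = 0.00655, and adjusted p = 0.329 with an estimated correlation). Ncr1, the NK receptor NKp46, had a log2 fold change of -2.97 ± 0.25, while Gzmb, the cytotoxic protease granzyme B, was higher in thymus at 2.17 ± 0.18. Genes of homing and tissue exit went both ways, with 11 of 24 higher, 9 lower and 22 passing when adjusted over the list alone (camera adjusted p = 0.949, with a negative test direction beside a median of 0.04), and with RLE factors 8 were higher and 11 lower. Ccr9, a chemokine receptor for gut homing, was 56.2 CPM ± 2.58 in thymus and 302 ± 47.1 in MLN (SD, n = 2 per group). Among inhibitory and TNF family receptors, Pdcd1, which encodes PD-1, had a log2 fold change of 2.71 ± 0.17 and Cd274, which encodes its ligand PD-L1, one of -2.09 ± 0.07. In that list 5 of 16 genes rose and 6 fell, with 11 passing when adjusted over the list alone, and the median of 0.19 and the negative test direction differed in sign (camera adjusted p = 0.927). None of the 14 list calls of this comparison held with an estimated correlation.

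**Figure D2:**
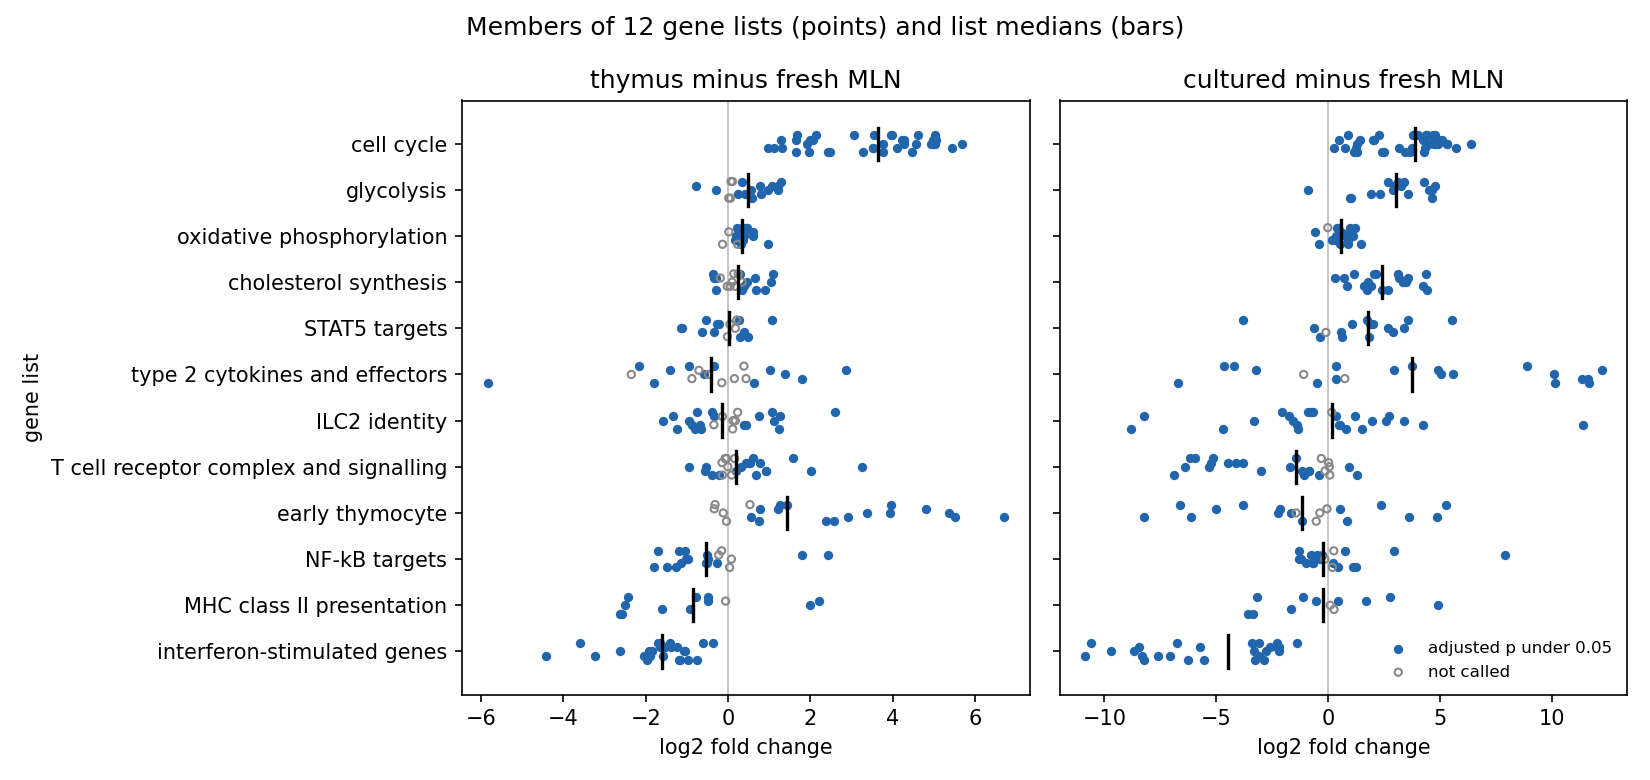
Log2 fold changes of the members of 12 gene lists in thymus against fresh MLN and in cultured against fresh MLN. Points are genes, filled when the adjusted p was under 0.05, genes with 0 to 3 counts in a group stand at their bound or counting ratio (left out where both groups are that low), and bars are list medians. All 26 interferon-stimulated genes lie below 0 and all 38 cell cycle genes above 0 in both comparisons.

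The comparison of cultured with fresh MLN cells asks what a week with IL-7, IL-25 and IL-33, cytokines that activate ILC2, changed. The cells came to express type 2 cytokines at high levels, and Id1, interferon-stimulated genes and the homing receptor Ccr9 fell. Il13 was 10175 CPM ± 147 in cultured and 9.03 ± 1.51 in fresh cells (SD, n = 2 per group), and it was the most abundant gene of both cultured libraries. Il5 was 8363 CPM ± 883 in cultured and 2.60 ± 0.116 in fresh cells (SD, n = 2 per group), a 3210-fold difference. Id1 was 1.33 CPM ± 0.207 in cultured and 451 ± 24.4 in fresh cells (SD, n = 2 per group), a 340-fold difference in the other direction. The edgeR test called 12592 of 16231 genes, 77.6% of those tested, of which 6403 were higher and 6189 lower after culture. The share of called genes that were higher was 50.8%, 49.8% to 52.1% with upper-quartile and RLE factors, and 41.8% with library totals alone, where 5382 were higher and 7498 lower. A test against a 2-fold change called 3189 higher and 2487 lower. The 2 groups did not overlap for 89.2% of the genes tested, where chance gives 33.3%.

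Of 21 genes for type 2 cytokines and effectors, 14 rose and 5 fell, with 19 passing when adjusted over the list alone. The median log2 fold change was 3.73 (camera adjusted p = 0.0215, and adjusted p = 0.428 with an estimated correlation). Il9, a growth factor for mast cells and ILC2, had 3 counts over the fresh libraries and was higher after culture by a counting ratio of 4730 (95% interval 1620 to 22900). Penk, the precursor of enkephalins, had a log2 fold change of 11.60 ± 0.17, an error likely too small at 11 counts over the fresh libraries. Il22, a cytokine known from ILC3 that acts on epithelium, had no counts in fresh cells and was at least 2240-fold higher after culture. Genes of ILC2 identity divided evenly, with 12 of 25 higher, 12 lower and 24 passing when adjusted over the list alone. The list was not called (camera adjusted p = 0.996), and its median of 0.15, mean of -0.33 and negative test direction differed in sign. Tph1, the rate-limiting enzyme of serotonin synthesis outside neurons, was 2808 CPM ± 273 in cultured and 1.06 ± 0.0431 in fresh cells (SD, n = 2 per group). Gata3 rose by a log2 fold change of 0.78 ± 0.07, while Rora fell at -2.07 ± 0.13, Il7r at -1.42 ± 0.08 and Thy1 at -1.57 ± 0.10. Il1rl1 had a log2 fold change of 0.32 ± 0.07 (adjusted p = 0.00093), a call lost with library totals alone (0.10, adjusted p = 0.21). Zbtb16, which encodes PLZF, a factor of ILC precursors, had no counts in cultured cells and was at least 448-fold lower, from 19.5 CPM ± 13.0 in fresh cells (SD, n = 2). With either fresh library left out that bound was 238 or 665.

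Among E proteins and their inhibitors, Id1 had a log2 fold change of -8.41 ± 0.11 (adjusted p = 7.7e-15), while Id2, the Id protein that ILC normally rely on, had one of 0.52 ± 0.07. Id3, another Id protein, was chosen after its values were seen. It had 3 counts over the fresh libraries and was 2.79 CPM ± 0.198 in cultured cells (SD, n = 2). It was higher after culture by a counting ratio of 71 (95% interval 23.9 to 347). Tcf12, which encodes the E protein HEB, fell at -1.09 ± 0.07. Of these 6 genes 2 rose and 2 fell, with 4 passing when adjusted over the list alone (camera adjusted p = 0.705). Of 25 genes of the T cell receptor complex and its signalling, 18 fell and 2 rose, with 20 passing when adjusted over the list alone. The median was -1.45 (camera adjusted p = 5.49e-05, and adjusted p = 0.428 with an estimated correlation). Trbc1, a constant segment of the T cell receptor beta chain, had a log2 fold change of -6.17 ± 0.09 and Cd6, a T cell surface receptor, one of -6.41 ± 0.29. Tcf7 was 0.772 CPM ± 0.195 in cultured and 234 ± 19.2 in fresh cells (SD, n = 2 per group), and Dtx1, a target of Notch, had a log2 fold change of -6.15 ± 0.15. Genes of homing and tissue exit were lower for 14 of 24 and higher for 5, with 19 passing when adjusted over the list alone and no call for the list (camera adjusted p = 0.0612). Ccr9 had a log2 fold change of -9.30 ± 0.20, and Klf2, a transcription factor of lymphocyte quiescence and trafficking, one of -5.09 ± 0.15.

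All 38 cell cycle genes rose after culture (37 with upper-quartile factors or library totals alone), with 38 passing when adjusted over the list alone and a median of 3.89 (camera adjusted p = 1.95e-13, and adjusted p = 0.428 with an estimated correlation). Birc5, survivin, had a log2 fold change of 5.32 ± 0.12. All 21 genes of cholesterol synthesis rose, with 21 passing when adjusted over the list alone and a median of 2.38 (camera adjusted p = 1.05e-08, and adjusted p = 0.428 with an estimated correlation). Fdps, farnesyl diphosphate synthase, was 116 CPM ± 2.97 in cultured and 5.63 ± 0.0354 in fresh cells (SD, n = 2 per group). Of 18 glycolysis genes 17 rose and 1 fell, with 18 passing when adjusted over the list alone and a median of 3.04 (camera adjusted p = 2.87e-08, and adjusted p = 0.428 with an estimated correlation). Slc2a3, a glucose transporter, had a log2 fold change of 4.78 ± 0.09, and Slc16a3, a lactate exporter, one of 4.61 ± 0.09. Of 21 nuclear genes of oxidative phosphorylation 18 rose and 2 fell, with 20 passing when adjusted over the list alone and a median of 0.56 (camera adjusted p = 0.00337, and adjusted p = 0.681 with an estimated correlation). Of 7 transcripts of the mitochondrial genome 6 rose, with 6 passing when adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.594 with an estimated correlation). Of 11 heat shock genes 10 rose and 1 fell, with 11 passing when adjusted over the list alone (camera adjusted p = 0.0422, and adjusted p = 0.428 with an estimated correlation). Without cultured MLN replicate 1 the heat shock list was no longer called (adjusted p = 0.0512).

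Of 16 STAT5 target genes 12 rose and 3 fell, with 15 passing when adjusted over the list alone and a median of 1.76 (camera adjusted p = 0.00643, and adjusted p = 0.43 with an estimated correlation). Il2ra, the alpha chain of the IL-2 receptor, had a log2 fold change of 3.36 ± 0.09 and Socs3, a feedback inhibitor of cytokine signalling, one of 5.52 ± 0.10, while Bcl2, which opposes cell death, fell at -3.79 ± 0.11. Among 20 NF-kB targets 7 rose and 10 fell, with 17 passing when adjusted over the list alone. That list was not called (camera adjusted p = 0.739), and its median of -0.22 and mean of 0.33 differed in sign. Irf4, a transcription factor induced on lymphocyte activation, had a log2 fold change of 7.91 ± 0.11. Among inhibitory and TNF family receptors 8 of 16 rose and 6 fell, with 14 passing when adjusted over the list alone (camera adjusted p = 0.547). Ctla4, an inhibitory receptor, was 150 CPM ± 0.939 in cultured and 0.207 ± 0.180 in fresh cells (SD, n = 2 per group), and Tnfrsf9, which encodes 4-1BB, had a log2 fold change of 8.50 ± 0.13.

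All 26 interferon-stimulated genes fell after culture, with 26 passing when adjusted over the list alone and a median of -4.48 (camera adjusted p = 1.58e-12, and adjusted p = 0.43 with an estimated correlation). Ifi44 was 0.143 CPM ± 0.0316 in cultured and 228 ± 6.46 in fresh cells (SD, n = 2 per group), and Oasl2, a member of the oligoadenylate synthetase family, had a log2 fold change of -9.70 ± 0.18. Macrophage and monocyte genes went both ways, with 11 of 15 lower, 4 higher, 15 passing when adjusted over the list alone and no call for the list (camera adjusted p = 0.148). Their summed level was 380 CPM in fresh and 293 in cultured cells. Cybb had a log2 fold change of -9.85 ± 0.20 and Lyz2 one of -5.21 ± 0.55, while Cst3, the most abundant of them after culture, rose at 1.91 ± 0.08.

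Markers of other granule-bearing and innate lymphoid cells went in both directions. Of 7 mast cell and basophil genes 6 rose and 1 fell, with 7 passing when adjusted over the list alone, a median of 6.96, or 5.08 with genes lacking counts at their bounds, and no call for the list (camera adjusted p = 0.153). Mcpt8, a basophil protease, was 727 CPM ± 197 in cultured and 0.209 ± 0.0321 in fresh cells (SD, n = 2 per group). Hdc, the enzyme of histamine synthesis, had a log2 fold change of 6.96 ± 0.21, while Cpa3, the mast cell carboxypeptidase, fell at -7.97 ± 0.20. Of 17 genes of NK cells and ILC1, 11 fell and 5 rose, with 16 passing when adjusted over the list alone and no call for the list (camera adjusted p = 0.177). Gzmb was 7189 CPM ± 2030 in cultured and 10.3 ± 0.999 in fresh cells (SD, n = 2 per group), while Klrb1c, which encodes NK1.1, had no counts in cultured cells and was at least 138-fold lower. Of 11 ILC3 genes 8 fell and 2 rose, with 10 passing when adjusted over the list alone, a median of -2.77, or -2.93 with genes lacking counts at their bounds, and camera adjusted p = 0.0411, and adjusted p = 0.428 with an estimated correlation. Ltb, lymphotoxin beta, had a log2 fold change of -6.36 ± 0.12 against the rise of Il22. The ILC3 call was lost with library totals alone (adjusted p = 0.0861), with a replicate block (0.0535) and without cultured MLN replicate 1 (0.0527). None of the 11 list calls of this comparison held with an estimated correlation.

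The comparison of cultured MLN with thymus cells completes the set of 3 groups, and in it organ and culture differ together. The type 2 cytokines Il5 and Il13 were higher in cultured cells by log2 fold changes of 11.49 ± 0.15 and 9.51 ± 0.15 (SE, n = 2 per group), and Id1 was lower at -8.32 ± 0.11. Csn1s1, the milk protein alpha-S1 casein, was 2641 CPM ± 121 in cultured and 0.451 ± 0.115 in thymus cells (SD, n = 2 per group). Sema3e, a guidance molecule, and Egfr, the epidermal growth factor receptor, had no counts in thymus and were at least 1990-fold and at least 400-fold higher in cultured cells. Zbtb16 and Cd163, a scavenger receptor, had no counts in cultured cells and were at least 1070-fold and at least 258-fold lower there. Cpa3 had a log2 fold change of -10.16 ± 0.18. Gata3 and Il1rl1 were each higher at 0.67 ± 0.07, while Thy1 was lower at -2.69 ± 0.10, Rora at -2.30 ± 0.13 and Il7r at -0.75 ± 0.08. The edgeR test called 11793 of 16231 genes, of which 5654 were higher and 6139 lower in cultured cells. The share of called genes that were higher was 47.9%, 51.0% with RLE factors and 35.1% with library totals alone. A test against a 2-fold change called 2429 higher and 2026 lower, so the balance depends on scaling and on the size of change asked for.

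Of 38 cell cycle genes, 12 were higher and 12 lower in cultured than in thymus cells, with 24 passing when adjusted over the list alone and a median of -0.03 (camera adjusted p = 0.976). The median, the mean of 0.01 and the positive test direction differed in sign, and with library totals alone 6 were higher and 22 lower. All 21 cholesterol synthesis genes were higher in cultured cells, with 21 passing when adjusted over the list alone and a median of 2.01 (camera adjusted p = 4.24e-10, and adjusted p = 0.315 with an estimated correlation). Of 26 interferon-stimulated genes 25 were lower in cultured cells, with 25 passing when adjusted over the list alone and a median of -2.93 (camera adjusted p = 2.04e-09, and adjusted p = 0.491 with an estimated correlation). Of 21 early thymocyte genes 17 were lower in cultured cells and 4 higher, with 21 passing when adjusted over the list alone and a median of -4.07, or -3.64 with genes lacking counts at their bounds (camera adjusted p = 0.00342, and adjusted p = 0.315 with an estimated correlation). Of 60 genes for cytosolic ribosomal proteins 31 were higher and 8 lower, with 39 passing when adjusted over the list alone and a median of 0.22 (camera adjusted p = 0.0199, and adjusted p = 0.796 with an estimated correlation). With library totals alone 13 were higher and 12 lower, and the list was not called (adjusted p = 0.392). None of the 9 list calls of this comparison held with an estimated correlation.

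Whether genes that differed between thymus and fresh MLN also moved on culture was asked across all 16231 genes. Genes called higher in thymus and higher after culture numbered 2867, against 1619 for independent calls. Those lower in both numbered 2547, against 1362. A further 597 genes were higher in thymus and lower after culture, against 1565, and 566 were lower in thymus and higher after culture, against 1409. Both comparisons use the same 2 fresh MLN libraries. In 20 simulations with no effect and the same sharing, a mean of 0.25 genes was called in both, so these simulations give no reference for the number of shared calls. The Pearson r of the log2 fold changes across genes was 0.4315, and the simulated values ran from 0.4541 to 0.53. With no effect, the sharing by itself sets r near these values, so they give no reference for an r over changed genes. The covariance was 1.263. In the simulations it reached at most 0.08365, the part that the modelled spread of the shared libraries gives by itself. A deviation common to both fresh MLN libraries was not simulated, and it would move a gene the same way in both comparisons. The 2 fresh MLN libraries cannot be divided between the comparisons with 2 in each. How much of the excess over independent calls comes from sharing those libraries was therefore not measured.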

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

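All alternatives were planned before the data were examined, except bounds and counting ratios with 1 library of the higher group left out, which were added after seeing the data: from both libraries to either one, Zbtb16 after culture went from 448 to 238 or 665 and Rag1 in thymus from 41.1 to 22.4 or 58.5. For the number of genes called, RLE, upper-quartile and library-total scaling, filters, protein-coding genes, a replicate block, a fit to 4 libraries and DESeq2 stayed within 1.5 times the main count, from 6430 to 8049 in thymus against MLN, 9487 to 13267 in cultured against fresh MLN and 9030 to 12269 in cultured MLN against thymus, with 0 genes called in opposite directions. A test against a 2-fold change called 1298, 5676 and 4455 genes, fewer because it asks for a larger change. Leaving out each library in turn gave 6148 to 7240, 11598 to 12953 and 10559 to 11994 genes, 12 to 16, 11 to 13 and 9 to 10 lists, and 4283 to 4916 genes moving the same way in both main comparisons (5414 with all libraries); a lone library is assumed to vary like the other groups. With an estimated correlation 0, 0 and 0 lists were called, against 14, 11 and 9. Camera then uses the 3 residual degrees of freedom, and lists with an estimate below 0.01 lost their calls too (Notch targets, -0.089). With this setting 5 of 5 simulated raised lists were called, but their members varied independently, which does not show how correlated lists fare. The cause of the lost calls was not tested. With fry 20, 31 and 25 lists were called, and cytosolic ribosomal proteins lost their call in thymus against MLN (adjusted p = 0.119) and cultured MLN against thymus (0.0887), where it was also lost with library totals (0.392) and without thymus replicate 1 (0.0821); the cause was not tested. The replicate block gave 8049, 12738 and 11944 genes and 13, 10 and 10 lists; the labels do not pair the libraries, and deviations of equal replicate numbers correlated across genes at 0.034 for MLN and cultured, 0.115 for MLN and thymus and 0.021 for cultured and thymus. Calls of named genes were lost 79 times in thymus against MLN over all alternatives (45 with the test against a 2-fold change, 23 with a library left out, 3 with DESeq2), 20 times in cultured against fresh MLN (19 with the 2-fold test) and 3 times in cultured MLN against thymus (3 with the 2-fold test). In thymus against MLN, 4 genes that were not called took the opposite sign or 0: with 1 library left out their log2 fold changes ranged from -0.3 to 0.01 for Ccr3, -0.68 to 0.4 for Lcn2, -0.19 to 0.38 for Hba-a1 and 0 to 0.31 for Il5, and Lcn2 was at 0 with library totals; the cause was not tested. Depth limits genes near 3 counts, where folds are bounds or ratios.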

Other observations

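All tests of explanations in this part were chosen after the result was seen, and the genes of its first paragraphs were chosen after their values were seen. Csn2, which encodes the milk protein beta casein, was 589 CPM ± 38.3 in cultured and 0.118 ± 0.0212 in fresh MLN cells (SD, n = 2 per group), a log2 fold change of 12.25 ± 0.14. Csn1s2b, another casein gene, had no counts in fresh cells and was at least 308-fold higher. Cyp11a1, which starts steroid synthesis from cholesterol, was 2190 CPM ± 83.5 in cultured and 0.653 ± 0.0218 in fresh cells (SD, n = 2 per group). Il1r2, the decoy receptor for IL-1, had a log2 fold change of 11.64 ± 0.19, and Tnfrsf8, which encodes CD30, one of 11.44 ± 0.15. Lama5 and Col18a1, components of basement membranes, had log2 fold changes of 11.11 ± 0.14 and 10.48 ± 0.12. The growth factor Areg, amphiregulin, rose by 8.86 ± 0.12 and the regulatory cytokine Il10 by 11.34 ± 0.18. Il10 had 5 counts over the fresh libraries, and its error in thymus against fresh MLN was 0.73, so 0.18 is too small. Mt1 and Mt2, metallothioneins that bind zinc and copper, rose by 9.29 ± 0.18 and 9.92 ± 0.16. Csn2 had 9 counts and Mt2 had 11 over the fresh libraries, so their errors are likely too small as well.

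Fresh MLN cells were the highest of the 3 groups for Ret, Vipr2 and Il17rb. Ret, the receptor for glial-derived neurotrophic factors, was 396 CPM in fresh MLN, 63.6 in thymus and 1.19 in cultured cells. Vipr2, a receptor for vasoactive intestinal peptide, was 278 CPM in fresh MLN, 27.7 in thymus and 4.97 in cultured cells. Il17rb, a chain of the IL-25 receptor, was 2910 CPM in fresh MLN, 1650 in thymus and 112 in cultured cells. Thymus cells were highest for Igfbp4, which binds insulin-like growth factors, at 421 CPM against 33.8 in fresh MLN and 3.01 in cultured cells. Sox4, a transcription factor of lymphoid progenitors, was 44.5 CPM in thymus, 8.51 in fresh MLN and 2.66 in cultured cells. These genes were each called in all 3 comparisons.

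Id1 was 340-fold lower after culture. The tables argue against scaling as the whole cause, since the log2 fold change ranged from -8.63 to -8.38 over RLE, upper-quartile and library-total scaling. Lower activity of the lck proximal promoter that drives the transgene stays open. Lck itself fell by 3.83 on the log2 scale (-3.83 ± 0.10), 14.3-fold, a smaller change than that of Id1. A count over the whole Lck gene does not measure that promoter by itself, so it cannot decide the question. Between the organs Id1 did not follow Lck. Lck was higher in thymus than in fresh MLN, at 0.5 ± 0.09 (edgeR adjusted p = 0.00048), while Id1 was not called (-0.09 ± 0.07). Cells without the transgene would go against the labels, which give the cultured cells, like the others, as homozygous for it. The counts cannot check this, because 0 features separate transgene from endogenous Id1 reads. Culture itself, with its cytokines and proliferation, stays open and untested.

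Mcpt8 and Hdc, known from mast cells and basophils, rose after culture. Outgrowth of cells that express Cpa3, Fcer1a, Ms4a2 and Gata2, abundant in mast cells and basophils, is argued against. The summed level of these markers, chosen after the result was seen, was 0.231 CPM in cultured cells, against 877 CPM for Mcpt8 and Hdc. Of 7 mast cell and basophil genes tested, 6 rose and 1, Cpa3, fell. Mcpt1, a mast cell protease, had no counts in fresh cells and was 10.2 CPM ± 4.97 in cultured cells (SD, n = 2). The sort was lineage-negative, which does not show which cells grew in culture. Outgrowth of cells low in the summed markers stays open. Reads of Gzmb counted on the related gene Mcpt8 are argued against as the whole cause, since Mcpt8 counts per Gzmb count were 0.1 to 0.102 in cultured, 0.0194 to 0.0211 in fresh MLN and 0.00488 to 0.00569 in thymus libraries. The difference between cultured and fresh MLN was 5-fold (exact 95% interval 3.04 to 8.74, counting error only), with 16 Mcpt8 counts over the fresh MLN libraries. Expression of Mcpt8 and Hdc by cultured ILC2 may account for the pattern, as a hypothesis drawn from the same data that was not itself tested.

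Interferon-stimulated genes were higher in fresh MLN than in thymus. A single library standing apart is argued against, since 26 of the 26 genes were lower in thymus whichever of the 4 libraries was left out. Macrophages or dendritic cells in the MLN libraries stay open. The cells were sorted as lineage-negative with Thy1 and ST2, which does not show how pure they were. The 25 marker genes of macrophages and dendritic cells differed by a median of 0.982 CPM (-8.80 to 141), many of them at low levels. The interferon-stimulated genes differed by a median of 158 CPM (36.7 to 899). Ctss (119 CPM), Cybb (68.9) and Bst2 (141, a member of both lists) lie within the range of the interferon-stimulated genes, while Lyz2 differed by 8.97 CPM and Cst3 by -8.80, and 8 of the 25 markers were at 5 CPM or more in cultured cells. A difference between the organs in exposure to interferon also stays open and untested.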
